A study of Mus musculus with 28 samples.

How the data were processed

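RNA was measured in 28 samples of 8-week-old female mice, 14 of duodenum and 14 of kidney cortex, with 6 wild-type (WT), 4 receptor-null (KO) and 4 AF2 samples per tissue. Per the labels' protocols, tissue was homogenised in TRIzol and libraries were made from total RNA with a QuantSeq kit, which reads the 3' ends of transcripts. The deposited tables hold raw counts per gene symbol and library, per the file headers, 1 table per tissue, with no normalisation. Sex, age and diet were taken from those headers. Genotype was taken from the sample titles, and the library code in each sample's description matched it to its column. Every column was used. The submitters' processing notes name the build mm10 and limma 3.34.9 without saying what limma was used for. The aligner, the counting tool, the use of strand and any filter are not given in the sources used here. Every deposited count was an even number (0 odd values in any library), so each read appears to have been counted 2 times. Statements about reads use the deposited counts divided by 2, and tests used the counts as deposited. Any 2 libraries of a group differed by more than sampling noise, with a smallest chi-square per degree of freedom of 5 in duodenum and 1.96 in kidney over genes with at least 20 reads in the pair, and 0 pairs of columns were identical.

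There were 31179 gene symbols for duodenum and 30227 for kidney, with 27271 in both. Of these 30294 (97.2%) and 29402 (97.3%) matched a gene name of GENCODE release vM21 on GRCm38 (mm10), which supplied the coordinates. Genes that share reads with near-identical copies or overlapping genes (pseudogenes, defensins, carboxylesterases, cytochrome P450 families, Methig1 with Mettl7a2) are uncertain, because the handling of such reads is not stated.

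Each tissue was analysed in edgeR 4.0.16 under R 4.3.3 with all 14 libraries in 1 fit. Genes were filtered with filterByExpr by group, libraries scaled by TMM, and contrasts of KO with WT, AF2 with WT and AF2 with KO tested by robust quasi-likelihood F tests, two-sided, with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that contrast. Standard errors are the absolute log2 fold change over the square root of F. All adjusted p-values of single genes are edgeR's unless another tool is named. CPM are counts scaled by TMM-adjusted library size and given as mean ± SD over libraries. The difference of an effect between tissues was tested as an interaction in 1 fit of all 28 libraries. Overlap of calls between KO and AF2, which share WT libraries, was set against independent lists, against 30 simulations of unchanged groups, and against fits that give each comparison 3 of the WT libraries, odd or even numbers.

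Gene lists of pathways and cell types were tested with camera (limma 3.58.1, preset correlation 0.01), 33 per tissue with at least 3 measured genes, adjusted over the lists of that tissue and contrast. An estimated correlation and fry were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. Designs, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names Vdr, a mineral panel for each tissue whether called or not, the 8 highest and 8 lowest fold changes among called genes with an average log2 CPM of at least 1, groups that do not overlap and a symbol that is not a predicted gene, up to 4 called members of each list with at least 3 called members or a camera call, and 5 genes each way for the interaction. Where a called list had no called member, the 2 members with the smallest p in the list's direction served as examples, chosen after their values were seen. Those genes did not pass over all genes tested.

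The duodenum and kidney steps were tested on simulated data with 200 changed genes. Genes were drawn independently, and no simulated library stood apart from its group. For AF2 against WT in duodenum the simulation gave 108 calls beside 9 real ones, and more calls make the adjusted threshold easier to pass. The shares below may therefore overstate recovery in the real data. For AF2 against WT, 94.1% of 4-fold, 44.3% of 2-fold and 18.8% of 1.5-fold changes were recovered in duodenum with 4 false calls over 12913 genes, and 95.6%, 69% and 22.5% in kidney with 4 false calls over 13152 genes. For AF2 against KO the shares were 89.7%, 39.3% and 10.1% in duodenum (2 false calls) and 94.1%, 65.5% and 18.3% in kidney (8 false calls). For the interaction in AF2 they were 90.3%, 48.4% and 7.6% over 14656 genes with 5 false calls, and with no simulated KO effect there were 0 false calls for KO. Of 100 genes changed alike and 50 changed in opposite directions in both mutants, 89 and 48 were called so in duodenum and 83 and 41 in kidney. A floor of 3 reads over the pooled group was used where a group had 0 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

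Alternatives were DESeq2 1.42.0, limma-voom, edgeR without robust fitting, RLE and upper-quartile scaling, no low-count filter or 1 CPM in at least 4 libraries, only the compared groups in the fit, a block for replicate number or for runs of consecutive library codes, a test against a 1.5-fold threshold, and each library left out in turn. Library codes fall into a run with WT 1 and WT 2, a run with WT 3, WT 4 and all KO libraries, and a run with WT 5, WT 6 and all AF2 libraries. Whether these runs were batches is not stated, and with them as a block a comparison with WT rests on 2 WT libraries. No sample was left out of the reported values. Some results for genes that the rule names are not reported here.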

Results

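RNA was sequenced from the duodenum and the kidney cortex of 8-week-old female mice with a normal vitamin D receptor gene (WT), without a working one (KO), or with a receptor that lacks activation function 2 (AF2), the surface through which the hormone-bound receptor recruits coactivators. All mice ate a diet rich in calcium, phosphate and lactose. Each tissue had 6 WT, 4 KO and 4 AF2 libraries, 28 in all. Library totals were 3713352 to 25181916 counts in duodenum, where WT 2 had the highest total and the next was 6519522, and 3725648 to 6492228 counts in kidney. After the expression filter 13302 genes were tested in duodenum and 13502 in kidney. The design sets absent receptor signalling against receptor signalling without coactivators and asks how each affects mineral homeostasis.

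Vdr, the targeted gene, lies on chromosome 15 at 97854425 to 97910630 on the minus strand (mm10). In duodenum its normalised count was 646, 537, 412, 267, 415 and 645 CPM in WT 1 to WT 6. It was 120.2, 114, 97.3 and 112 CPM in KO 1 to KO 4, and 408, 432, 362 and 388 CPM in AF2 1 to AF2 4. In kidney it was 208, 212, 193, 177, 181 and 212 CPM in WT, 22.1, 21.0, 17.1 and 7.94 CPM in KO, and 81.7, 85.0, 91.9 and 64.9 CPM in AF2. The libraries count tags at the 3' ends of transcripts, and a tag outside the deleted part of the gene would be counted in a KO mouse too. The sources used here do not say which part is deleted. In both tissues every KO library lay below every WT and AF2 library, while a remaining signal in KO says nothing of a working receptor.

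**Figure D1:**
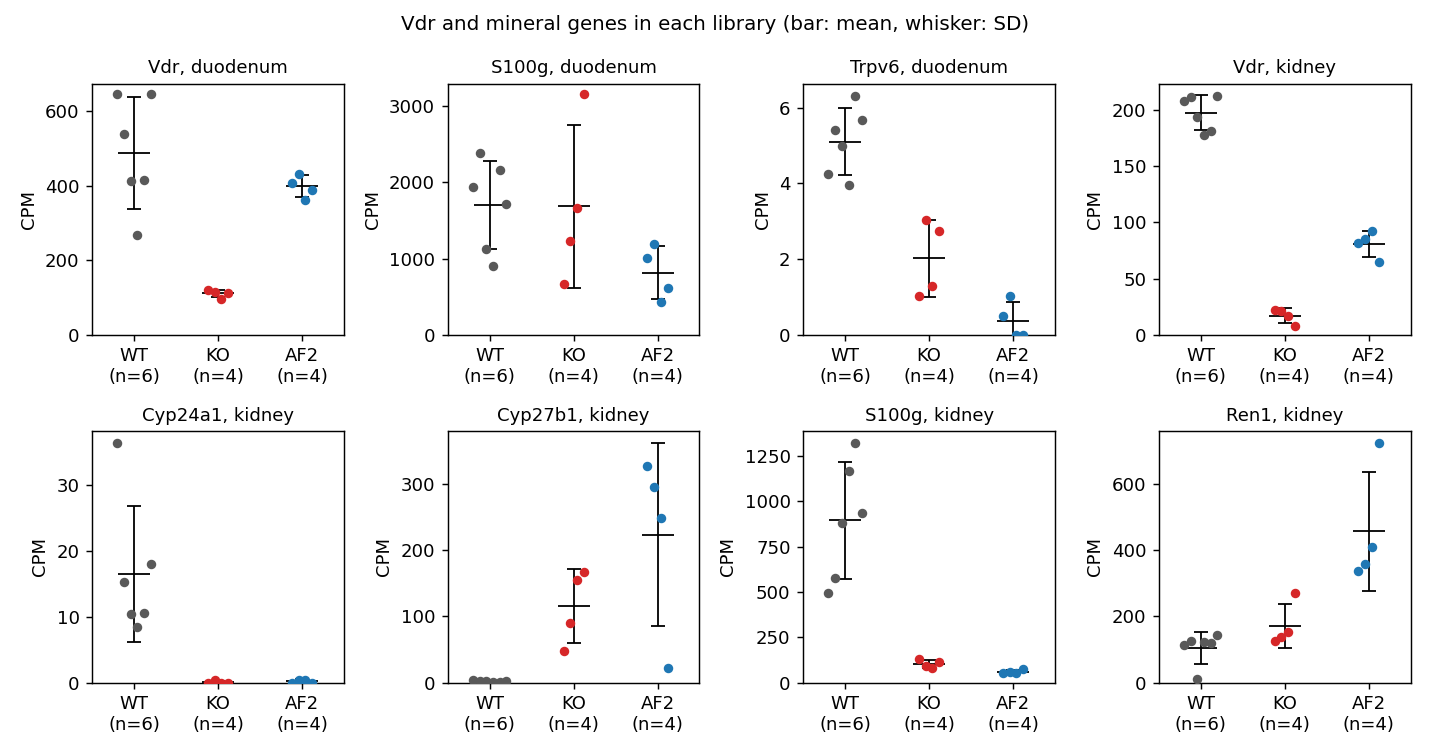
Normalised counts (CPM, y axis) of Vdr, S100g and Trpv6 in duodenum and of Vdr, Cyp24a1, Cyp27b1, S100g and Ren1 in kidney, 1 point per library for 6 WT, 4 KO and 4 AF2 libraries, with a bar at the mean and a whisker of 1 SD. In kidney S100g fell from a mean of 894 CPM in WT to 103 CPM in KO and 58.9 CPM in AF2, while in duodenum its KO mean was 1685 CPM beside 1705 CPM in WT.

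In the duodenum of KO mice 3 genes passed the test, all lower than in WT. Vdr fell from 487 ± 149.6 CPM (SD, n = 6) to 111 ± 9.72 CPM (SD, n = 4), a log2 fold change of -2.14 ± 0.20 (SE) with an adjusted p of 2.54e-05. Aldh4a1, a mitochondrial enzyme of proline breakdown, fell from 52.8 to 21.2 CPM (log2 fold change -1.32 ± 0.23, adjusted p 0.0284). Psmb9, a subunit of the immunoproteasome that trims peptides for antigen presentation, fell from 46.3 to 24.3 CPM (log2 fold change -0.93 ± 0.17, adjusted p 0.0284). The genes of transcellular calcium uptake did not pass. Trpv6 (chromosome 6, 41620624 to 41636405), the calcium channel of the apical membrane, measured 5.10 ± 0.887 CPM in WT and 2.02 ± 1.02 CPM in KO without overlap of the groups, at an adjusted p of 0.324 (log2 fold change -1.33 ± 0.52). S100g (chromosome X, 162961992 to 162964599), the cytosolic calcium-binding protein calbindin, differed by -0.02 ± 0.44 on the log2 scale (adjusted p 0.991). Adjusted p was 0.44 for Atp2b1, the basolateral calcium pump, 0.296 for Cldn2, which forms a paracellular cation pore, 0.917 for the manganese exporter Slc30a10 and 0.879 for the drug-metabolising enzyme Cyp3a11. Cyp24a1, whose product inactivates the hormone, had 0 counts in every duodenal library, which allows up to 0.119 CPM in WT, 0.363 in KO and 0.328 in AF2 by counting error alone. The phosphate cotransporter Slc34a2 had 0, 1 and 2 reads in the 3 genotypes.

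As sets, 15 of 33 gene lists shifted between KO and WT duodenum by camera with its preset correlation. Other counted splits of the same libraries had a median of 6 called lists, and 16 at most. The lists of the absorbing surface lay lower. All 19 measured genes of brush border digestion and sugar uptake had a lower mean in KO (median log2 fold change -0.43, adjusted p 2.91e-05, estimated-correlation adjusted p 0.376). None passed over all genes tested and 4 passed adjusted over the list alone, among them the glucose transporter Slc5a1 (3787 and 1897 CPM, adjusted p over all genes 0.0572) and the disaccharidase Sis (3599 and 2453 CPM, 0.0898). Lipid absorption and lipoprotein assembly lay lower too (median -0.33, 17 of 19 genes lower, adjusted p 0.000175, estimated-correlation adjusted p 0.417), with 0 genes over all genes tested and 5 adjusted over the list alone, Dgat2 of triglyceride synthesis among them (93.3 and 57.0 CPM). The interferon response had 19 of 19 genes lower (median -0.35, adjusted p 5.11e-05, estimated-correlation adjusted p 0.376; 4 genes adjusted over the list alone), with the antiviral genes Ifit3 at 13.1 and 5.89 CPM and Oasl2 at 54.0 and 37.6 CPM. Intestinal calcium transport and receptor targets had a median of -0.29 (12 of 15 genes lower, adjusted p 0.011, estimated-correlation adjusted p 0.376; 1 gene adjusted over the list alone). Among its lower members the smallest p were those of the phosphate-sugar exchanger Slc37a2 (78.6 and 40.0 CPM, p 0.000267) and the brush border myosin Myo1a (1139 and 910.4 CPM, p 0.0151), while Cldn2 lay higher (log2 fold change 0.40, p 0.0101). Bile acid handling (median -0.49, adjusted p 0.0227), phosphate transport (-0.30, 0.0392), antimicrobial and MHC class II genes (-0.38, 0.0379), oxidative phosphorylation (-0.15, 0.00715), immediate early genes (-0.39, 0.00715) and the circadian clock (-0.47, 0.0227) lay lower as well. Their estimated-correlation adjusted p was 0.376, 0.376, 0.541, 0.435, 0.417 and 0.376 in that order. The circadian output gene Dbp had means of 58.6 CPM in WT and 15.7 CPM in KO. Of these lists bile acid handling had 4 genes adjusted over the list alone, phosphate transport and immediate early genes 1 each, and the circadian clock 1 higher and 2 lower, while the other 2 had 0.

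The crypt lists of KO duodenum lay higher. Cell proliferation had 18 of 18 genes higher (median 0.34, adjusted p 5.55e-05, estimated-correlation adjusted p 0.417; 2 genes adjusted over the list alone), with thymidylate synthase Tyms at 18.02 CPM in WT and 30.7 CPM in KO. Intestinal stem cells had 8 of 8 genes higher (median 0.37, adjusted p 0.0227, estimated-correlation adjusted p 0.376; 0 genes adjusted over the list alone), with the stem-zone marker Olfm4 at 174 and 226 CPM. Paneth cells, the crypt cells that secrete antimicrobial peptides, had 8 of 10 genes higher (median 0.89, adjusted p 5.55e-05, estimated-correlation adjusted p 0.376; 7 genes adjusted over the list alone), led by the defensins Defa30 (729 and 1430 CPM) and Defa24 (1105 and 2091 CPM). Enteroendocrine cells (median 0.30, adjusted p 0.0109) and extracellular matrix and fibroblasts (0.18, 0.0454) lay higher (estimated-correlation adjusted p 0.376 and 0.464) with 1 and 0 genes adjusted over the list alone. Over the 15 lists the estimated-correlation adjusted p ran from 0.376 to 0.541, so no list was called with an estimated correlation.

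These 3 calls came from edgeR, with 1519 of 13302 genes at an unadjusted p under 0.05, while DESeq2 called 110 genes and limma-voom 2. With the counts halved edgeR called 8 genes, these 3 among them. In 293 genes the KO and WT groups did not overlap (2.2%, where chance gives 0.952%), all 3 called genes included. The count of calls followed single libraries, as the plot of calls with each library left out shows. It was 229 without WT 4, 13 without KO 2, 8 without WT 6, 5 without AF2 4, and 1 (Vdr) without any of WT 2, WT 3, WT 5, KO 3, AF2 1 and AF2 3. Aldh4a1 also lost its call without WT 1, KO 1 or KO 4 (adjusted p 0.0563, 0.147 and 0.122), and Psmb9 without WT 1, KO 1 or AF2 2 (0.0567, 0.156 and 0.0511). Without WT 4 camera called 16 lists. A fit with runs of consecutive library codes as a block, which leaves 2 WT libraries in the comparison, called 1 gene, Vdr. With that block camera called fewer lists. The direction reversed, without a call, for antimicrobial and MHC class II genes and for oxidative phosphorylation.

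In the duodenum of AF2 mice Trpv6 was nearly lost. It fell from 5.10 ± 0.887 CPM (SD, n = 6) to 0.377 ± 0.484 CPM (SD, n = 4), a log2 fold change of -3.56 ± 0.64 with an adjusted p of 0.0392. The AF2 value rests on 4 reads beside 127 in WT, a ratio of read rates of 12.1 with an exact 95% counting interval of 4.61 to 45.1. The other 8 called genes were not of mineral transport. Rising genes were Selenow, a selenoprotein (log2 fold change 0.83), Mrpl34 of the mitochondrial ribosome (0.60), the ubiquitin gene Ubb (0.60), the ribosomal protein gene Rps20 (0.56) and the ribosomal pseudogene Rpl31-ps8 (0.92), whose reads could be split with its parent gene. Falling genes were Ifih1, a sensor of viral RNA (-0.72), Cisd1, an iron-sulfur protein of the outer mitochondrial membrane (-0.77), and Plekha8 of lipid transfer (-0.88). Adjusted p was 0.0408 for Ubb and 0.0392 for the other 7. S100g had means of 1705 ± 582 CPM in WT and 814 ± 348 CPM in AF2 but did not pass (log2 fold change -1.07 ± 0.46, adjusted p 0.398). Vdr itself (-0.29 ± 0.18, adjusted p 0.566), Atp2b1 (adjusted p 0.572), Cldn2 (0.619), Slc30a10 (0.861) and Cyp3a11 (0.473) did not pass.

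By camera 10 of 33 lists shifted between AF2 and WT duodenum, where other counted splits of the same libraries had a median of 6 called lists, and 20 at most. Smooth muscle lay higher in 10 of 10 genes (median log2 fold change 0.47, adjusted p 1.27e-07, estimated-correlation adjusted p 0.554; 9 genes adjusted over the list alone), with desmin (Des) at 38.9 CPM in WT and 61.4 CPM in AF2 and calponin (Cnn1) at 59.7 and 88.4 CPM. Cholesterol biosynthesis lay lower in 21 of 23 genes (median -0.53, adjusted p 1.41e-06, estimated-correlation adjusted p 0.554; 9 genes adjusted over the list alone), with the enzymes Hsd17b7 at 59.5 and 34.3 CPM and Pmvk at 24.3 and 15.1 CPM. Brush border digestion and sugar uptake lay lower in 17 of 19 genes (median -0.35, adjusted p 0.00364, estimated-correlation adjusted p 0.691; 3 genes adjusted over the list alone), led by the brush border phosphatase Alpi at 3893 and 2230 CPM. Intestinal calcium transport and receptor targets had a median of -0.22 (adjusted p 0.0223, estimated-correlation adjusted p 0.554). It held the 1 list member called over all genes tested, Trpv6, and 2 adjusted over the list alone. Xenobiotic metabolism (median -0.21, adjusted p 0.0223), the interferon response (-0.27, 0.0413) and immediate early genes (-0.32, 0.0223) lay lower (estimated-correlation adjusted p 0.748, 0.691 and 0.691), with 1, 0 and 0 genes adjusted over the list alone. Extracellular matrix and fibroblasts (0.27, 0.00408), Paneth cells (0.47, 0.0413) and enteroendocrine cells (0.34, 0.00624) lay higher (estimated-correlation adjusted p 0.554, 0.748 and 0.554), with 1, 0 and 2 such genes, and the peptide hormone genes Ghrl (26.2 and 42.2 CPM) and Cck (86.9 and 125 CPM) led the enteroendocrine list. Estimated-correlation adjusted p ran from 0.554 to 0.748 over the 10 lists, and no call held.

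The 9 calls came from edgeR, with 1564 genes at an unadjusted p under 0.05. DESeq2 called 154 genes, 8 of the 9 among them, and limma-voom 0. The groups did not overlap in 363 genes (2.73%, chance 0.952%), all 9 called genes included. None of the 9 kept its call in every fit with 1 library left out. The count was 217 without WT 4, 1 without WT 1 or WT 2, and 0 without WT 3, WT 6, KO 3, AF2 1, AF2 3 or AF2 4. Adjusted p of Trpv6 without these 8 libraries was 0.0788, 0.0687, 0.082, 0.0902, 0.0512, 0.0939, 0.085 and 0.216, and its log2 fold change in those fits lay between -3.64 and -3.17. Rpl31-ps8 kept its call without WT 1. Some of the other 8 also lost the call without WT 5 (adjusted p 0.0643 to 0.0747 in Rpl31-ps8, Rps20, Cisd1 and Ifih1), without AF2 2 (0.0509 to 0.0772 in Rpl31-ps8, Ubb, Plekha8, Cisd1 and Ifih1) or without KO 4 (0.0562 in Ubb). Without WT 4 camera called 16 lists. With library codes as a block edgeR called 131 genes, 6 of the 9 among them.

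**Figure D2:**
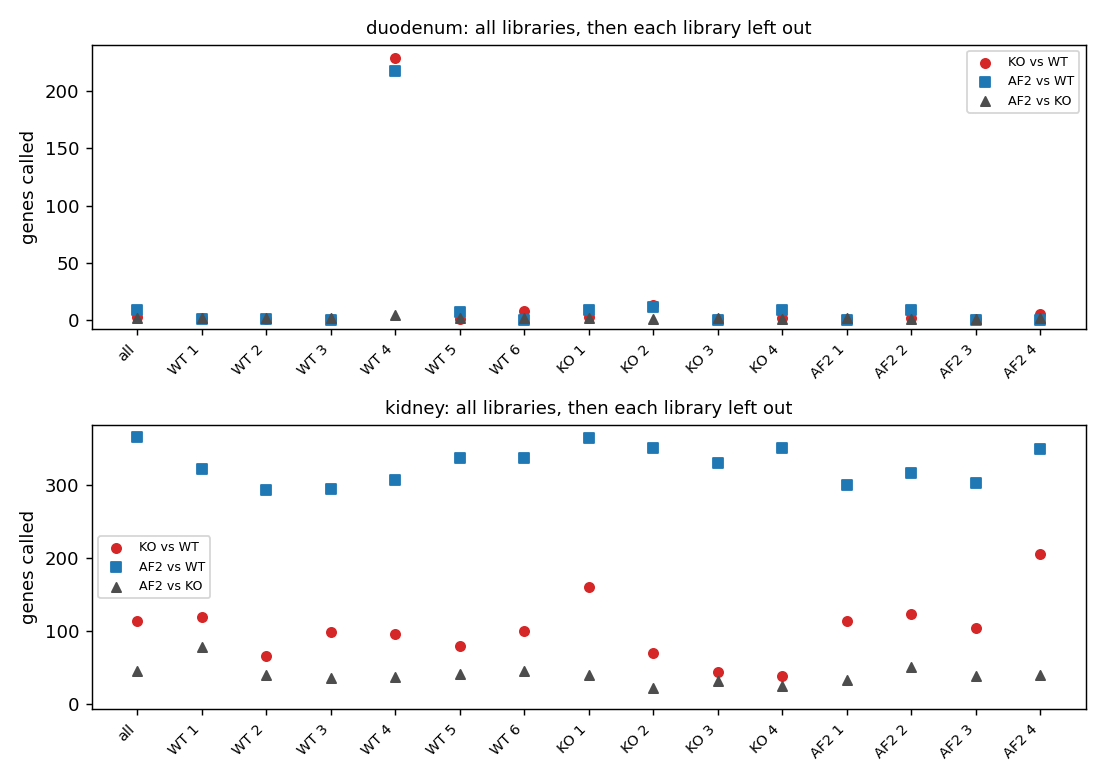
Number of genes called by edgeR (y axis) with all libraries and with each library left out in turn (x axis), for KO against WT, AF2 against WT and AF2 against KO in duodenum and kidney. In duodenum the counts were 3, 9 and 2 with all libraries and rose to 229 and 217 for the comparisons with WT when WT 4 was left out.

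Between AF2 and KO duodenum 2 genes were called, both higher in AF2. Vdr rose with a log2 fold change of 1.84 ± 0.21 and an adjusted p of 0.000492. Slpi, a secreted inhibitor of neutrophil proteases, rose from 16.5 ± 1.27 to 35.8 ± 6.76 CPM (SD, n = 4 each) with a log2 fold change of 1.13 ± 0.20 and an adjusted p of 0.0326, and its WT mean was 24.0 CPM. Trpv6 (-2.23 ± 0.71, adjusted p 0.235) and S100g (-1.05 ± 0.49, adjusted p 0.514) did not pass, nor did Atp2b1 (adjusted p 0.93), Cldn2 (0.741), Slc30a10 (0.82) or Cyp3a11 (0.704). Smooth muscle lay higher in 10 of 10 genes (median 0.53, camera adjusted p 8.72e-08, estimated-correlation adjusted p 0.785; 9 genes adjusted over the list alone). Cholesterol biosynthesis lay lower in 20 of 23 genes (median -0.30, camera adjusted p 0.0125, estimated-correlation adjusted p 0.785; 0 genes adjusted over the list alone). Camera called only these 2 lists, fewer than the median of 4.5 in other splits of the same libraries. The means of Des were 37.4 CPM in KO and 61.4 CPM in AF2, and those of Pmvk 23.2 and 15.1 CPM. By edgeR 1328 genes had an unadjusted p under 0.05. DESeq2 called 93 genes, with 1 of the 2 edgeR calls among them, and limma-voom 1. The groups did not overlap in 873 genes (6.56%, where chance gives 2.86%). Without WT 4 edgeR called 4 genes, and without KO 2, KO 4, AF2 2 or AF2 3 it called 1. Slpi lost its call without KO 1, KO 2, KO 3, KO 4, AF2 2 or AF2 3 (adjusted p 0.106, 0.0559, 0.143, 0.178, 0.17 and 0.0846). All KO and AF2 libraries belong to different runs of library codes, so these genotypes meet only through the WT libraries when codes are a block, and that fit called 5 genes, neither Vdr (log2 fold change 1.20, adjusted p 0.0523) nor Slpi (0.79, 0.443) among them.

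No gene was called against WT in both KO and AF2 duodenum by edgeR, with 1519 and 1564 genes at an unadjusted p under 0.05. DESeq2 found 9 shared calls in the same direction and limma-voom 0. Without WT 4 there were 38. Fold changes of the 2 comparisons correlated across genes with r = 0.402 and a covariance of 0.0624. Simulated unchanged groups gave a mean r of 0.388 (30 simulations, highest 0.434) and a mean covariance of 0.0458 (highest 0.0539), which leaves a difference of 0.0166. In each simulation both comparisons shared 6 WT libraries that were simulated too, with genes drawn independently and no library standing apart as WT 4 did. Genes are not independent replicates. With 3 WT libraries given to each comparison, r was 0.11 and 0.112 and the covariance 0.0217 in both arrangements.

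The kidney of KO mice had 114 called genes, 39 higher and 75 lower than in WT, and 45 of them differed more than 2-fold. The genes of hormone synthesis and breakdown moved in opposite directions. Cyp27b1 (chromosome 10, 127048250 to 127053006), whose enzyme makes the active hormone, rose from 1.87 ± 0.907 CPM (SD, n = 6) to 115 ± 55.7 CPM (SD, n = 4), a log2 fold change of 5.93 ± 0.79 (adjusted p 0.00445). Cyp24a1 (chromosome 2, 170482708 to 170497145) fell from 16.5 ± 10.3 CPM to 1 read in 4 libraries beside 233 reads in WT. Its ratio of read rates was 167 with an exact 95% counting interval of 29.7 to 6630, and its adjusted p was 5.09e-06. Among calcium-handling genes S100g fell from 894 ± 323 to 103 ± 21.9 CPM (log2 fold change -3.12 ± 0.31, adjusted p 0.000376). The other panel genes did not pass. Adjusted p was 0.94 for the apical calcium channel Trpv5, 0.105 for the calcium-binding protein Calb1 (377 and 501 CPM), 0.124 for the calcium exchanger Slc8a1, 0.79 and 0.89 for the phosphate cotransporters Slc34a1 and Slc34a3, 0.992 for the FGF23 coreceptor Kl, 0.136 for the parathyroid hormone receptor Pth1r and 0.7 for renin (Ren1). Vdr fell by 3.54 on the log2 scale (SE 0.20, adjusted p 1.62e-10).

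Further genes were called in KO kidney. Amdhd1 (1.69 to 13.3 CPM, adjusted p 3.89e-05) and Ftcd (4.81 to 17.7 CPM, adjusted p 6.36e-05), enzymes of successive steps of histidine breakdown, both rose. Eef1akmt3, a lysine methyltransferase gene beside Cyp27b1 in the opposite orientation (127031004 to 127041513), rose from 4.72 to 26.8 CPM (adjusted p 0.000963). The cytochrome P450 gene Cyp2d9 rose (log2 fold change 2.02) and Cyp4b1, which oxidises fatty acids and foreign compounds, fell from 97.6 to 22.4 CPM (adjusted p 0.0245). The ETS transcription factors Etv1 (20.3 to 1.69 CPM, adjusted p 0.000476) and Etv5 (8.42 to 2.09 CPM, adjusted p 0.0087) fell, as did Nepn, an extracellular inhibitor of TGF-beta signalling (25.2 to 4.35 CPM), and Acy3, an aminoacylase of the proximal tubule (714 to 443 CPM). Methig1 fell from 26.9 to 1.16 CPM (log2 fold change -4.62 ± 0.30, adjusted p 2.97e-11) and Mettl7a2 rose from 38.2 to 171 CPM (adjusted p 0.0119). These 2 methyltransferase-like genes overlap on the plus strand of chromosome 15 (100353149 to 100384436 and 100353200 to 100361840), so the division of reads between them is uncertain. AW822252 (log2 fold change 2.15) and Timd2, a receptor for ferritin (1.92), also rose.

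By camera 7 of 33 lists shifted between KO and WT kidney. The circadian clock lay lower (median log2 fold change -0.42, adjusted p 0.0118, estimated-correlation adjusted p 0.336). Of its 14 genes 1 rose (Clock, log2 fold change 0.53) and 2 fell (Ciart, -2.62, and Tef, -0.49), against 2 higher and 6 lower adjusted over the list alone. The thick ascending limb lay higher (median 0.31, adjusted p 0.0118, estimated-correlation adjusted p 0.361) with 1 gene called over all genes tested and 1 adjusted over the list alone. It was Slc12a1, the loop diuretic-sensitive salt cotransporter (856 to 1170 CPM, adjusted p 0.0356). The distal convoluted tubule (median 0.25, adjusted p 0.0118, estimated-correlation adjusted p 0.336) had 0 called genes and 4 adjusted over the list alone, with the magnesium channel Trpm6 at 22.5 and 35.1 CPM and the kinase Wnk1 at 728 and 945 CPM. Renal magnesium and sodium transport (median 0.18, adjusted p 0.0205, estimated-correlation adjusted p 0.336) had 1 called gene, Slc12a1, and 7 adjusted over the list alone, 6 higher and 1 lower. Intercalated cells (median 0.31, adjusted p 0.0118, estimated-correlation adjusted p 0.361) had 0 called genes and 2 adjusted over the list alone. FGF and ERK feedback genes lay lower (median -0.32, adjusted p 0.0409, estimated-correlation adjusted p 0.422) with Etv5 called, also adjusted over the list alone. The proximal straight tubule passed as lower (adjusted p 0.045, estimated-correlation adjusted p 0.361) with a median of -0.36 but a mean of 0.03, with Acy3 called and 5 genes adjusted over the list alone, 1 higher and 4 lower. No list was called with an estimated correlation.

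The 114 calls came from edgeR, while DESeq2 called 220 genes and limma-voom 123. The groups did not overlap in 465 genes (3.44%, chance 0.952%), among them 99 of the 114. Calls numbered 206 without AF2 4, 66 without WT 2, 70 without KO 2, 44 without KO 3 and 38 without KO 4. Vdr, Cyp24a1, Cyp27b1 and S100g kept their calls without any library. Cyp4b1 lost its call without WT 2 (adjusted p 0.063), KO 2 (0.1), KO 3 (0.115) or KO 4 (0.121), Ciart without KO 2 (0.0502), KO 3 (0.0533) or KO 4 (0.0625), Etv5 without KO 3 (0.0548) or KO 4 (0.0522), Timd2 without KO 3 (0.0574) or KO 4 (0.109) and Mettl7a2 without KO 3 (0.0548). Clock, Tef and Slc12a1 lost theirs without WT 2, WT 3, WT 4, WT 5, KO 2, KO 3 or KO 4 (adjusted p 0.0553 to 0.244), and without AF2 2 (Clock, 0.0512), AF2 3 (Tef, 0.0506) or AF2 1 (Slc12a1, 0.0529). With library codes as a block 25 genes were called, 24 of them among the 114, and Cyp27b1 lost its call (adjusted p 0.257) with no smaller fold change.

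The kidney of AF2 mice had 366 called genes, 146 higher and 220 lower than in WT, and 131 of them differed more than 2-fold. Cyp27b1 rose to 223 ± 138 CPM (SD, n = 4), a log2 fold change of 6.88 ± 0.78 (adjusted p 0.000473). It was 327, 294 and 248 CPM in AF2 1, AF2 2 and AF2 3 and 21.5 CPM in AF2 4. Cyp24a1 fell to 2 reads in 4 libraries, a ratio of read rates of 74.3 (exact 95% counting interval 20.3 to 617, adjusted p 3.46e-06). S100g fell to 58.9 ± 12.04 CPM (log2 fold change -3.92 ± 0.32, adjusted p 2.7e-05). Vdr fell to 80.9 ± 11.5 CPM (log2 fold change -1.29 ± 0.17, adjusted p 6.16e-05). Renin had means of 106 ± 48.1 CPM in WT and 457 ± 179.8 CPM in AF2, without overlap of the groups, but stayed above the threshold (log2 fold change 2.12 ± 0.52, adjusted p 0.0576). The remaining panel genes did not pass, with adjusted p of 0.552 for Trpv5, 0.25 for Calb1, 0.651 for Slc8a1, 0.464 for Slc34a1, 0.659 for Slc34a3, 0.462 for Kl and 0.586 for Pth1r.

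Further genes were called in AF2 kidney, some of them as in KO kidney. Cyp7b1, which hydroxylates oxysterols, rose from 2.29 to 30.8 CPM (adjusted p 0.00187), and the carbonic anhydrase Car3 rose from 17.0 to 146 CPM (adjusted p 0.00176). Car3 was 249 CPM in AF2 4 and 109.5 to 115 CPM in the other AF2 libraries. It is also among the 3 measured genes of the adipocyte list, which camera called in no comparison (smallest adjusted p 0.107). The mean log2 CPM of that list was 5.27 to 6.32 in AF2 libraries and 3.80 to 5.54 in WT libraries. Amdhd1 (17.3 CPM, adjusted p 2.57e-06), Ftcd (32.1 CPM, adjusted p 5.02e-08), Eef1akmt3 (49.2 CPM, adjusted p 1.19e-05), AW822252 (21.5 CPM) and Cyp2d9 (32.8 CPM) rose as in KO kidney. Etv1 (1.38 CPM, adjusted p 0.000123), Nepn (2.94 CPM) and Cyp4b1 (12.2 CPM, adjusted p 0.00151) fell. The carboxylesterase Ces1d fell from 334 to 52.0 CPM (adjusted p 0.015), and Chrdl1, an antagonist of bone morphogenetic proteins, from 8.97 to 0.749 CPM (adjusted p 0.028). Bhmt, which remethylates homocysteine, fell to 3 reads beside 45 in WT, a ratio of 9.57 (exact 95% counting interval 3.07 to 48.1, adjusted p 0.0223).

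By camera 10 of 33 lists shifted between AF2 and WT kidney, 3 higher and 7 lower. Renal calcium handling lay lower (median log2 fold change -0.21, adjusted p 0.0241, estimated-correlation adjusted p 0.122). S100g and the pore-forming Cldn2 (330 to 215 CPM) fell and uromodulin (Umod) rose (1741 to 2490 CPM), the same 3 counts over all genes tested and adjusted over the list alone. The connecting tubule lay lower (median -0.35, adjusted p 0.0117, estimated-correlation adjusted p 0.122) with S100g its 1 called gene by either adjustment. Renin angiotensin genes lay lower (median -0.26, adjusted p 0.0416, estimated-correlation adjusted p 0.134). Of its genes 2 fell over all genes tested, among them the angiotensin-processing peptidase Ace (45.5 to 20.2 CPM, adjusted p 2.7e-05), and adjusted over the list alone 1 rose and 2 fell. Xenobiotic metabolism lay lower (median -0.59, adjusted p 0.00971, estimated-correlation adjusted p 0.122) with Cyp4b1 and the organic anion exporters Abcc2 (237 to 157 CPM) and Abcc3 (29.3 to 15.1 CPM) called by either adjustment. FGF and ERK feedback genes (median -0.41, adjusted p 0.00971, estimated-correlation adjusted p 0.244) had 1 called gene, Etv5 (1.65 CPM in AF2), and 3 adjusted over the list alone. The proximal tubule (median -0.23, adjusted p 0.0452, estimated-correlation adjusted p 0.34) had 1 called gene, the organic anion transporter Slc22a8 (937 to 477 CPM), and 5 adjusted over the list alone, 2 higher and 3 lower. The interferon response (median -0.45, adjusted p 0.048, estimated-correlation adjusted p 0.585) had 0 by either adjustment, with the interferon-induced GTPase Gbp3 at 26.9 and 12.8 CPM.

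Intercalated cells, podocytes and the thick ascending limb were the 3 lists that lay higher in AF2 kidney. Intercalated cells (median log2 fold change 0.23, adjusted p 0.00971, estimated-correlation adjusted p 0.34) had 3 called genes, the anion channel Aqp6 (44.4 to 88.9 CPM), the bicarbonate exchanger Slc4a1 (13.6 to 23.7 CPM) and the proton pump subunit Atp6v0d2 (48.7 to 74.1 CPM), and 4 adjusted over the list alone. Slc4a1 also belongs to the blood list, which was not called (adjusted p 0.0635) but had its highest means in AF2 4, KO 4 and AF2 1. Podocytes (median 0.21, adjusted p 0.0416, estimated-correlation adjusted p 0.134) had 2 called genes, among them Synpo, which binds actin in podocyte foot processes (40.3 to 65.9 CPM), and 3 adjusted over the list alone. The thick ascending limb (median 0.29, adjusted p 0.0452, estimated-correlation adjusted p 0.481) had Umod and Slc12a1 called by either adjustment. Ammoniagenesis and gluconeogenesis was not called as a list (adjusted p 0.405), and its median of -0.15 and mean of 0.12 differ in sign. Of its 12 genes 4 rose, the glutamine transporter Slc38a3 (21.2 to 42.5 CPM), Fbp1 of gluconeogenesis (717 to 1105 CPM) and the ammonia transporters Rhcg (45.8 to 78.8 CPM) and Rhbg (35.9 to 54.7 CPM). No list was called with an estimated correlation.

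The 366 calls came from edgeR, while DESeq2 called 530 genes and limma-voom 350. The groups did not overlap in 639 genes (4.73%, chance 0.952%), among them 289 of the 366. Leaving out 1 library gave 294 to 365 genes. Chrdl1 lost its call without AF2 1, AF2 2, AF2 3 or AF2 4 (adjusted p 0.0813, 0.0651, 0.0643 and 0.109), and Bhmt without WT 3, AF2 2 or AF2 3 (0.0583, 0.0785 and 0.083). Slc12a1 lost it without WT 3, WT 5, AF2 1 or AF2 3 (0.0653, 0.0599, 0.0834 and 0.0508), and Slc4a1 without WT 2, WT 3, WT 5, AF2 1 or AF2 4 (0.054, 0.0511, 0.0594, 0.0676 and 0.0949). Rhbg lost it without WT 2, WT 3, WT 4, WT 6, AF2 2, AF2 3 or AF2 4 (0.0508 to 0.165), and Abcc3 without WT 1, WT 2, WT 5, KO 1, KO 3, AF2 1, AF2 3 or AF2 4 (0.0519 to 0.14). With library codes as a block 121 genes were called, 109 of them among the 366, and Cyp27b1 lost its call (adjusted p 0.0726) with no smaller fold change.

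Between AF2 and KO kidney 45 genes were called, 27 higher and 18 lower in AF2. Calb1, the calcium-binding protein of the distal nephron, was lower in AF2 (501 ± 128 CPM in KO, 310.0 ± 17.7 CPM in AF2, n = 4 each, log2 fold change -0.69 ± 0.13, adjusted p 0.0106), with a WT mean of 377 CPM. Slc8a1, which carries calcium out of the same cells, had means of 377 and 232 CPM without overlap of the groups and did not pass (adjusted p 0.0768). The choline phosphodiesterase Enpp6 (108 to 55.6 CPM, adjusted p 0.000293), the lipid droplet protein Fitm1 (18.7 to 6.88 CPM, adjusted p 0.00467) and the insulin-degrading enzyme Ide (69.9 to 33.1 CPM, adjusted p 0.000925) were lower in AF2. Vdr (2.26 ± 0.20, adjusted p 1.29e-06), Methig1 (5.53 ± 0.31, adjusted p 3.88e-13), Smagp, an epithelial adhesion protein (53.2 to 104 CPM, adjusted p 0.000293) and Cyp7b1 (2.85 to 30.8 CPM, adjusted p 0.043) were higher. S100g (adjusted p 0.351), Cyp27b1 (0.614), Cyp24a1 (0.852) and renin (0.386) did not pass, nor did Trpv5 (0.764), Slc34a1 (0.867), Slc34a3 (0.906), Kl (0.569) or Pth1r (0.507).

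By camera 5 of 33 lists shifted between AF2 and KO kidney. Renal calcium handling (median log2 fold change -0.23, adjusted p 0.00723, estimated-correlation adjusted p 0.0722) and the connecting tubule (-0.56, 0.00723, estimated-correlation adjusted p 0.0722), which share members, lay lower, with Calb1 the 1 called gene of each and 2 and 3 genes adjusted over the list alone. The distal convoluted tubule lay lower in 8 of 8 genes (median -0.28, adjusted p 0.00723, estimated-correlation adjusted p 0.0789) with 0 called genes and 3 adjusted over the list alone, Trpm6 (35.1 and 21.3 CPM) and Wnk1 (945 and 744 CPM) having the smallest p. The circadian clock lay higher (median 0.60, adjusted p 0.00723, estimated-correlation adjusted p 0.218) with Tef called (220.2 to 362 CPM, adjusted p 0.00847) and 7 genes adjusted over the list alone, 6 higher and 1 lower. Podocytes lay higher (median 0.32, adjusted p 0.00723, estimated-correlation adjusted p 0.0722) with 1 called gene and 2 genes adjusted over the list alone. No list was called with an estimated correlation.

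The 45 calls came from edgeR, while DESeq2 called 151 genes and limma-voom 42, and the groups did not overlap in 967 genes (7.16%, chance 2.86%), 44 of the 45 among them. Calls numbered 78 without WT 1, 22 without KO 2 and 24 without KO 4. Of 19 named genes called, 11 lost the call in some fit without 1 library and 8 kept it. Calb1 lost its call without KO 4 (adjusted p 0.0977, log2 fold change -0.49), and Cyp7b1 without WT 2, WT 3, WT 4, WT 5, KO 1, KO 2, KO 4, AF2 1 or AF2 4 (0.0588 to 0.171). With library codes as a block, where KO and AF2 meet only through the WT libraries, 1 gene (Methig1) was called.

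KO and AF2 kidney shared 80 calls in the same direction, 24 higher and 56 lower, with 1 gene (Methig1) called in opposite directions. Independent lists of the same sizes would share 1.64 genes in the same direction. Unchanged groups that shared WT libraries, all of them simulated with independent genes, had at most 1 such call in common. Fold changes correlated across genes with r = 0.554 beside a simulated mean of 0.395 (0.37 to 0.417), and their covariance was 0.0952 beside 0.0362, a difference of 0.059. Neither comparison value holds both real effects and shared WT libraries. With 3 WT libraries given to each comparison the shared calls numbered 27 and 42, r was 0.325 and 0.299, and the covariance 0.0662 and 0.0617. Leaving out WT 2, KO 2, KO 3 or KO 4 lowered the shared calls to 48, 52, 34 and 29.

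**Figure D3:**
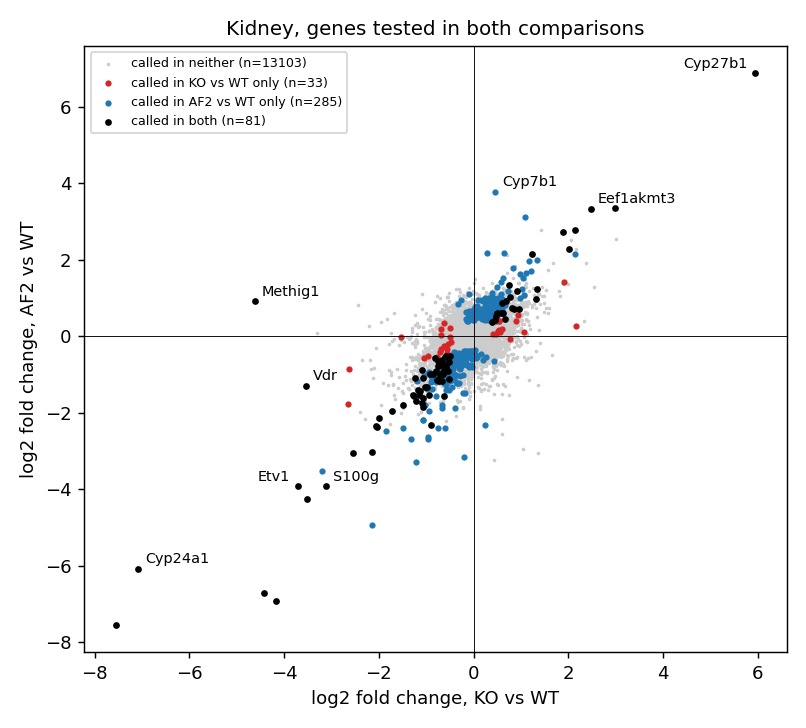
Log2 fold change of each tested kidney gene in KO against WT (x axis) and in AF2 against WT (y axis), coloured by the comparison in which edgeR called it. Of the called genes 33 were called in KO alone, 285 in AF2 alone and 81 in both, 80 of these in the same direction.

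Whether an effect differed between the tissues was tested as an interaction over 14944 genes. The effect of KO differed in 8 genes, 3 more positive in duodenum and 5 in kidney, and the effect of AF2 in 57, 32 and 25. S100g was among both sets. Its KO effect was -0.02 in duodenum and -3.12 in kidney, a difference of 3.06 ± 0.54 (adjusted p 0.0401), and its AF2 effect -1.07 and -3.92, a difference of 2.83 ± 0.54 (adjusted p 0.0206). Etv1 fell in kidney, with -0.12 and 0.47 in duodenum (difference 3.54 ± 0.64 for KO, adjusted p 0.0222, and 4.36 ± 0.64 for AF2, adjusted p 0.00022). Eef1akmt3 rose in AF2 kidney with -1.13 in duodenum (difference -4.47 ± 0.57, adjusted p 4.07e-05), and Cyp7b1 likewise with -0.36 in duodenum (difference -4.18 ± 0.85, adjusted p 0.0198). Aldh4a1 had the opposite pattern in KO, lower in duodenum and not in kidney (difference -1.68 ± 0.27, adjusted p 0.0123). The effect on Vdr was not shown to differ, with a difference of 1.37 ± 0.29 for KO (adjusted p 0.0704) and 0.97 ± 0.28 for AF2 (adjusted p 0.134), and neither was that on Trpv6 in AF2 (adjusted p 0.359), which had under 1 CPM in kidney. Of the 11743 genes tested in both tissues 1 (Vdr) was called in both for KO and 0 for AF2 by edgeR, where independent lists would share 0.019 and 0.181. Of the kidney calls tested in duodenum, 49 of 76 (64.5%) for KO and 160 of 266 (60.2%) for AF2 had the same sign there.

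The 8 interaction calls for KO came from edgeR, which gave 1194 genes an unadjusted p under 0.05, while DESeq2 called 66 and limma-voom 2, and for AF2 the counts were 57, 1598, 187 and 28. Among duodenal libraries, the KO count was 23 without WT 4, 13 without WT 5 or KO 4, 5 without KO 1 or AF2 1, 3 without WT 2 or WT 6 and 2 without KO 2. Among kidney libraries it was 21 without KO 1, 14 without AF2 4, 5 without WT 2, 4 without WT 1 or KO 2, 3 without WT 5, 2 without WT 6, AF2 1 or AF2 2, 1 without KO 4 and 0 without KO 3. The AF2 count was 123, 33, 26, 24, 20 and 19 without WT 4, WT 5, AF2 1, WT 2, AF2 4 and AF2 3 of duodenum, and 32, 28 and 23 without AF2 4, WT 2 and AF2 1 of kidney. Etv1 and Eef1akmt3 kept their AF2 calls in all 28 such fits. S100g lost its AF2 call without duodenal AF2 1 (adjusted p 0.0545) or kidney AF2 1 (0.0593) and its KO call in 10 of 28 fits (largest adjusted p 0.137). Etv1 lost its KO call without duodenal KO 1 (0.0682), kidney KO 3 (0.108) or kidney KO 4 (0.0792), Aldh4a1 without kidney KO 3 (0.0552), and Cyp7b1 without duodenal WT 2 (0.0624), AF2 1 (0.058) or AF2 3 (0.0579). The interaction fit took all 28 libraries as independent, though same-numbered libraries of the 2 tissues may come from the same mouse. With those libraries joined as a block, 11 of the named interaction calls were lost.

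In duodenum 15 lists passed camera in no comparison, with the smallest adjusted p of a list from 0.0883 to 0.746. It was 0.0883 for enteric neurons and glia and for pancreatic acinar cells, 0.106 for adipocytes and for myeloid cells, 0.11 for iron, zinc and manganese handling, 0.117 for T cells, 0.167 for endothelial cells, 0.245 for distal small intestine and 0.249 for blood. It was 0.266 for vitamin D metabolism and uptake, 0.326 for Brunner gland and stomach, 0.328 for tuft cells, 0.481 for B and plasma cells, 0.668 for goblet cells and 0.746 for the integrated stress and unfolded protein response. For pancreatic acinar cells in AF2 the median (-0.28) and the mean (-0.19) were negative while the test pointed up. The mean log2 CPM of this list varied widely within each genotype. It ran from 0.796 (WT 2) to 9.81 (WT 3) in WT, 2.42 to 8.86 in KO and 4.31 to 8.92 in AF2. Whether uneven amounts of pancreas in the duodenal samples affected other results was not tested. In kidney 19 lists passed in no comparison. The smallest adjusted p was 0.0635 for blood, 0.0889 for ammoniagenesis and gluconeogenesis, 0.107 for adipocytes, 0.136 for kidney injury, 0.205 for cholesterol biosynthesis, 0.232 for endothelial cells and for phosphate transport, 0.273 for immediate early genes, 0.282 for B and plasma cells and for collecting duct principal cells and 0.401 for vitamin D metabolism and uptake. It was 0.406 for myeloid cells, 0.542 for oxidative phosphorylation, 0.563 for inner medulla, for smooth muscle and for iron, zinc and manganese handling, 0.64 for extracellular matrix and fibroblasts, 0.801 for the integrated stress and unfolded protein response and 0.809 for cell proliferation. T cells and adrenal cortex had 1 measured gene each in kidney and were not tested.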

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

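The tests of duodenal WT 4 and of genes nearly missing in kidney AF2 4 were chosen after these results were seen, while those of kidney AF2 4 as a WT or KO sample or another cell mix were written before.

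The effects of a mutation on several genes differed between duodenum and kidney in the interaction test, given here as duodenum minus kidney on the log2 scale. For KO the difference was 3.54 for the transcription factor Etv1, 3.06 for the calcium-binding protein S100g and 0.79 for the kinase anchor Pakap. It was -0.91 for the ethanolamine kinase Etnk1, -0.98 for Tspan13, -1.99 for the phosphate-sugar exchanger Slc37a2, -1.68 for Aldh4a1 and -1.09 for the sulfatase Sulf2. For AF2 it was 4.36 for Etv1, 3.41 for Chrdl1, 2.83 for S100g, 2.32 for the transcription factor Sox9 and 2.08 for the membrane glycoprotein Gpm6a. It was -4.47 for Eef1akmt3 and -4.18 for Cyp7b1. Ftcd (-6.53), Wscd1 (-5.16) and Wdr91 (-3.51) also passed, but their AF2 duodenum means were 0, 0 and 0.119 CPM beside WT means of 0.379, 0.475 and 1.25 CPM, so these fitted values are no measure of size. In the fits without 1 of the 28 libraries, Etv1, Gpm6a and Eef1akmt3 kept their AF2 calls in all 28, and Ftcd lost its call in 21. Chrdl1, Sox9, Wscd1 and Wdr91 lost their AF2 calls in 8 fits each. Among the KO calls Etnk1 and Sulf2 lost theirs in 17, Pakap and Tspan13 in 14 and Slc37a2 in 12.

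Single libraries stood apart from their group in 10 of 93 groups tested, where chance gives 4.7. WT 2 of duodenum had 25181916 counts, the others at most 6519522. The 10 most abundant genes took 17.1% of counts in duodenal AF2 4 and 14.01% to 14.39% in the other AF2 libraries. Slc30a10 was 160.5 CPM in duodenal AF2 4 beside 272 CPM or more, and Cldn2 216 CPM in duodenal KO 4 beside 165 CPM or less. Slc34a2 in duodenal KO 3 (0.427 CPM) and AF2 2 (0.676 CPM) and Cyp24a1 in kidney KO 2 (0.412 CPM) stood apart because the other 3 libraries had 0 counts. Cyp24a1 was 36.3 CPM in kidney WT 1, the others at most 17.9 CPM. Renin was 9.75 CPM in kidney WT 3 and at least 112 CPM in the other WT libraries. The first principal component of kidney AF2 4 was 63.7, that of the other AF2 libraries 8.4 to 11.1.

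Leaving out duodenal WT 4 raised the calls from 3 to 229 in KO and from 9 to 217 in AF2. Over the 200 genes that best separated the genotypes without it, WT 4 lay at 0.881 on a scale from the other WT libraries (0) to the KO mean (1), where the other WT libraries lay at -0.263 to 0.306 and the KO libraries, each over genes chosen without it, at 0.4 to 0.757, all below WT 4. On the scale to the AF2 mean it lay at 0.785, within the AF2 libraries' 0.511 to 0.872, with the other WT libraries at -0.204 to 0.303. A KO sample under a WT label is argued against by its Vdr of 267 CPM, since no KO library exceeded 120.2 CPM and it lay 5.68 SD from the KO mean on the log2 scale, with the SD pooled over the genotypes without WT 4. An AF2 sample under that label stays open, with values for and against it. Its Vdr lay below the AF2 range of 362 to 432 CPM, at -5.30 SD of the AF2 libraries alone but -2.56 of the pooled SD, within the bound of 3 used for both genotypes. That bound was put on the pooled SD after these values were seen. Its Trpv6 (3.96 CPM, 9 reads) lay above the highest AF2 value of 1.01 CPM but rests on few reads. Another mix of cell types stays open too. WT 4 was an extreme of the WT libraries in 0 of 17 marker lists and lay outside their range in 5, while the other WT libraries lay outside in 4 to 7. No other explanation was tested.

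Kidney AF2 4 lay apart from all other kidney libraries, with 225 of 9423 genes more than 2-fold and 37 more than 4-fold below every other library, where no other library had more than 7 and 1. On the upper side kidney WT 1 had 25 genes more than 2-fold and 7 more than 4-fold above every other library, where no other kidney library had more than 2 and 0. The cause in WT 1 was not tested. A WT or a KO sample under the label of AF2 4 is argued against. Over 349 genes called without it AF2 4 lay at 0.869 from WT (0) to the other AF2 libraries (1), with a 95% interval of 0.818 to 0.963, and over 40 genes at 0.882 from KO (0.622 to 1.09). These intervals come from resampling the genes, which are not independent, and hold no spread between libraries. The other AF2 libraries, each over genes called without it, lay at 0.767 to 0.858 from WT and 0.664 to 0.869 from KO. For the genes nearly missing, another mix of cells stays open. Of 67 ribosomal protein and oxidative phosphorylation genes, expressed in all cells, 8 were more than 2-fold below every other library. Of these 3 were more than 4-fold below, while the median of that class was 0.09 higher. But 2 of the 3 were among the largest drops that prompted the test, which leaves 1 outside them, and the bound was changed after the value was seen. Whether the library as a whole holds another mix cannot be told apart from chance. It lay outside the range of the others in 5 of 16 marker lists, above it for smooth muscle, blood and endothelial cells and below it for the connecting tubule (6.967 beside at least 7.003), a list called lower in AF2, and collecting duct principal cells (4.817 beside at least 5.029), where 2.29 are expected and WT 1 reached 4. The rule for this count was changed after the value was seen, to ask for an excess over chance. In duodenal AF2 4, 7 of 212 of these genes lay below all other libraries, with 15.1 expected, so the pattern was not shared by the samples of that number. A fault in this library remained untested, and its Cyp27b1 of 21.5 CPM against at least 248 CPM in the other AF2 libraries belongs to the same library.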

How the results depend on the processing

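Alternatives chosen after seeing the data were the halved counts, the thinned WT 2, camera without duodenal WT 4 or kidney AF2 4, and limma-voom and DESeq2 without WT 4. The others were planned. The cause was not tested unless one is given.

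RLE scaling and the 1 CPM filter kept every count of genes within 1.5 times, and list counts were not run with them. For duodenum KO against WT (3 genes with all libraries) DESeq2 called 110, edgeR without robust fitting 1, without a low-count filter 215, with library codes as a block 1, with the 1.5-fold threshold 1, with halved counts 8 and with WT 2 thinned 7. For AF2 against WT (9) the counts were 154 by DESeq2, 0 by limma-voom, 0 without robust fitting, 26 with upper-quartile scaling (21 higher and 5 lower, against 5 and 4 with TMM), 240 without filter, 0 with only the compared groups, 131 with the code block, 0 with the threshold and 14 with WT 2 thinned. For AF2 against KO (2) they were 93 by DESeq2, 1 by limma-voom, 1 without robust fitting, 106 without filter, 50 with only the compared groups, 5 with the code block, 1 with the threshold and 1 with WT 2 thinned. Without WT 4, limma-voom called 175, 109 and 1 genes and DESeq2 561, 546 and 131. Shared calls in duodenum (0) were 9 by DESeq2 and 38 without filter.

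For kidney KO against WT (114) the counts were 220 by DESeq2, 252 without filter, 177 with only the compared groups, 25 with the code block and 15 with the threshold. For AF2 against WT (366) they were 590 without filter, 121 with the code block and 55 with the threshold, and for AF2 against KO (45) 151 by DESeq2, 193 without filter, 1 with the code block and 3 with the threshold. Shared kidney calls (80) were 128 by DESeq2, 153 without filter and 18 with the code block. Interaction calls were 66 by DESeq2, 2 by limma-voom and 23 without filter for KO (8), and 187 by DESeq2 and 28 by limma-voom for AF2 (57). Dropping the filter raised edgeR's median prior degrees of freedom from 15.2 in duodenum and 19.1 in kidney to infinity, so that the median gene took its spread wholly from the fitted trend. The code block left 2 WT libraries in each comparison with WT, and whether this or an effect of the runs moved its counts was not tested. A larger required change by construction lowers the calls under the threshold.

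Leaving out 1 library gave 1 to 229, 0 to 217 and 1 to 4 genes in duodenum for KO and AF2 against WT and AF2 against KO, 38 to 206, 294 to 365 and 22 to 78 in kidney, 0 to 38 and 29 to 108 shared calls in duodenum and kidney, and 0 to 23 and 19 to 123 interaction calls for KO and AF2. Without WT 4 the median prior degrees of freedom in duodenum was 17.6.

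Camera calls fell to 0 in all 6 comparisons with an estimated correlation. In duodenum fry called 0 lists one way in KO (15 by camera), AF2 (10) and AF2 against KO (2), and 3, 1 and 1 in either direction. The code block gave 4 in KO and 11 in AF2 against KO, and leaving out WT 4 gave 16 in AF2. In the code block the duodenal KO direction reversed for antimicrobial and MHC class II genes (adjusted p 0.649) and oxidative phosphorylation (0.855). In kidney fry in either direction called 11 lists in KO (7) and 18 in AF2 (10), and the code block gave 3 in KO and 1 in AF2 against KO (5).

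Replicate numbers were not shown to pair samples within a tissue. Same-numbered libraries within a tissue correlated at -0.199 to 0.102 in duodenum and -0.036 to 0.171 in kidney in their deviations from group means. Same-numbered libraries of the 2 tissues correlated at -0.052 to 0.071 (median 0.0245, other pairs -0.004). Of 14 duodenal libraries 10 correlated best with the kidney library of their own number, among the 4 or 6 of their genotype. Unpaired samples would be unlikely to give so many, so the same mice may have given both tissues. This is a hint from the data and not from the design. With replicate number as a block, calls in duodenum were 2, 1 and 14 for KO, AF2 and AF2 against KO, calls in kidney 79, 338 and 52, interaction calls 6 and 36 for KO and AF2, and lists 8 in KO and 6 in AF2 duodenum and 2 in KO kidney. The block moved no other count by more than 1.5 times. In the interaction it joined same-numbered libraries of the 2 tissues, while the main fit took all 28 libraries as independent. Of the named interaction calls 11 were lost under the block, and 2 were gained.

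Of the named genes called, those that kept their call under every setting numbered 1 of 3, 0 of 9 and 0 of 2 in duodenum for KO, AF2 and AF2 against KO, 10 of 21, 14 of 35 and 1 of 19 in kidney, and 0 of 8 and 3 of 10 for the interaction in KO and AF2. None of these genes reversed. Small effects were seldom called, as 1.5-fold changes were recovered in 18.8% of simulated genes in duodenum and 22.5% in kidney for AF2 against WT. Whether depth, spread or the number of libraries sets this limit was not tested.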

Other observations

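The tests of genes near Vdr and of shared reads of Methig1 and Mettl7a2 were chosen after their results were seen, and the counts of other splits were planned.

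Of the kidney genes called between AF2 and KO, 2 are given as examples that lay further from WT in AF2 than in KO mice, without a count over all genes. The choline phosphodiesterase Enpp6 had means of 165 CPM in WT, 108 in KO and 55.6 in AF2, and the lipid droplet protein Fitm1 34.5, 18.7 and 6.88 CPM.

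The circadian clock list was called in kidney for KO against WT and AF2 against KO, and in duodenum for KO against WT but not for AF2 against KO (adjusted p 0.176). No call held with an estimated correlation (adjusted p 0.336, 0.218 and 0.376). In kidney the clock repressor Ciart had means of 5.59 CPM in WT, 0.934 in KO and 3.07 in AF2, Clock 50.5, 72.6 and 56.8 CPM, and Tef 309, 220.2 and 362 CPM. Of these only Tef was called between AF2 and KO (adjusted p 0.00847, against 0.198 for Ciart and 0.311 for Clock), and Ciart of KO (up to 2.06 CPM) overlapped AF2 (from 1.40 CPM). Tef lies within 20 Mb of Vdr on chromosome 15, where genes called between AF2 and KO gathered. In duodenum Dbp had means of 58.6 CPM in WT, 15.7 in KO and 55.1 in AF2, and Nr1d2 123, 66.1 and 118 CPM, without passing in KO against WT (adjusted p 0.175 and 0.231) or AF2 against KO (0.214 and 0.296), and Dbp of KO (up to 27.6 CPM) overlapped WT (from 25.4 CPM). The hour at which tissues were taken is not given in the sources used here, and most clock genes follow it.

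Other splits of the same libraries were counted for each result. In kidney the real split alone gave as many genes, in 1 of 100 splits for KO against WT (114, highest other 13), in 1 of 100 for AF2 against WT (366, highest other 4), in 1 of 35 for AF2 against KO (45, highest other 3) and in 1 of 100 for the 80 shared calls (highest other 1). The interaction counts of 8 and 57 were reached in 1 of 100 splits each (highest others 6 and 3). No other counted split reached these values, and 1 of 100 or 1 of 35 is the smallest share these splits can give. For the shared calls the splits shuffled all genotype labels, which removes both mutant effects at once. That share therefore does not test whether KO and AF2 share more calls than their separate effects and common WT libraries would give. An effect of the runs of library codes cannot be excluded, since all KO libraries lie in 1 run and all AF2 libraries in another. With the runs as a block the 4 kidney counts were 25, 121, 1 and 18, and without kidney KO 3 the KO interaction count was 0. For lists in kidney the counts were as large in 5 of 100 splits for KO (7, highest other 9), 1 of 100 for AF2 (10, highest other 6) and 3 of 35 for AF2 against KO (5, highest other 7). The real split thus stood alone for AF2 against WT, and chance cannot be excluded for the other 2.

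In duodenum 4 of 100 splits called as many genes as the real one for KO (3, highest other 318) and 4 of 100 for AF2 (9, highest other 385), and 1 of 35 for AF2 against KO (2, highest other 1). The highest counts came from splits that joined WT 4 to KO 1, KO 3 and KO 4 or to AF2 1, AF2 3 and AF2 4. Splits that call many times the real count point to a structure of the samples beyond the genotype labels, so the share under 0.05 does not separate the duodenal calls against WT from that structure. For AF2 against KO no other split called as many genes as the real one. But 1 of its 2 calls was Vdr, the targeted gene itself, and the highest other split also called 1, so this share says little of other genes. The KO count of 3 includes Vdr too. For lists the counts were as large in 4 of 100 splits for KO (15, highest other 16), 27 of 100 for AF2 (10, highest other 20) and 27 of 35 for AF2 against KO (2, highest other 12). The median of the other splits was 6, 6 and 4.5 lists in that order. Chance cannot be excluded for the last 2. For KO the real split did not stand alone either, since another split called more lists, so its share does not separate these lists from the structure of the samples. With 0 shared calls in duodenum all 100 of 100 splits gave as many (highest other 1), which a real count of 0 fixes in advance, so this share tests nothing.

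Genes called between AF2 and KO kidney gathered near Vdr on chromosome 15. Of 43 located called genes other than Vdr, 6 (13.95%) lay within 20 Mb of it, against 2.15% of all tested genes, an odds ratio of 7.52 (95% interval 2.57 to 18.2, two-sided Fisher exact p 0.000291, adjusted 0.00175 over 6 comparisons). They were Methig1, Smagp, Slc11a2, Lima1, Tef and Gtpbp1, all higher in AF2. Gtpbp1 lost its edgeR call without KO 2 (adjusted p 0.0636), KO 4 (0.0551) or AF2 4 (0.0573). For KO against WT 7 of 111 lay within 20 Mb of Vdr (p 0.00997, adjusted 0.0299), Cyp2d9 and Mettl7a2 among them. For AF2 against WT it was 9 of 365 (p 0.584), with Aqp6 and Cyp2d9 among them. Of the 6 genes near Vdr called between AF2 and KO, 5 were tested in duodenum. There 4 had the same sign and 1 (Tef) an unadjusted p under 0.05. Of 28 called genes elsewhere 20 had the same sign and 5 such a p, a like share. The excess is consistent with DNA of another strain flanking a targeted allele, which may differ between the mutant lines. A local effect of the altered locus on its neighbours would also place changes there and was not tested. Reads shifting between Methig1 and Mettl7a2 are argued against as the source of the rise of Mettl7a2 in KO, because the sum of both rose from 65.1 ± 17.1 CPM (n = 6) to 172 ± 33.5 CPM (n = 4; exact permutation p 0.00476 over 210 arrangements). A shift stays open for the fall of Methig1, whose loss was 19.3% of the gain of Mettl7a2.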
